A study of Mus musculus with 34 samples.

How the data were processed

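RNA was sequenced from 28 libraries of mouse cells in 9 groups: 3 genotypes (control, heterozygous deletion of the 7qF3 region, and duplication on 1 chromosome with deletion on the other) at 3 stages of differentiation. The stages were embryonic stem cells (ESCs), neural progenitor cells (NPCs) taken at day 5, and immature neurons of the ventral midbrain lineage taken at day 16. Total RNA libraries were stranded and read as paired ends of 75 bases, per the labels. For 1 group, NPCs with duplication and deletion, a description label named the deletion only; the title and the genotype label named both, and these were used. The series also lists 6 Hi-C samples, for which no files were at hand; chromosome contacts are not analysed here.

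Expected counts per gene and library were deposited by the authors, made with STAR 2.6.0c and RSEM 1.3.0 on the mouse build mm9, per the submitters' processing notes. These values were neither scaled nor log-transformed, and 6392 of 29968 gene entries held a value that was not whole. The authors' deposited table also gave, for 6 comparisons of a mutant with control, a log2 fold change of mutant over control with its standard error. The p-value and adjusted p-value of each comparison in that deposited table came from DESeq2 1.22.2, per the submitters' processing notes; the design of that test and its filter on expression are not stated. Whether the strand was used in counting is not stated either. Counts of genes that overlap an antisense or host transcript therefore cannot be assigned to 1 transcript, and neither can counts of the clustered protocadherins, which share constant exons (Pcdha, Pcdhg) or are near-identical (Pcdhb).

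The expected counts were rounded, and 92 spike-in entries were left out, which leaves 29876. Spike-in shares were 1.8%, 0.732% and 0.738% in ESC replicate 1 and at most 5.08e-06% elsewhere. Depth per library, with spike-ins included here and below, ran from 5578151 to 78814037 counts. The largest entry took 19.6% to 38.8% of the counts of a library. Symbols were matched to current mouse gene names and their synonyms: 22264 entries matched, and 654 symbols were synonyms that shared 1 current gene with other entries, over 1316 entries in all. These were tested as deposited. Of 33 pairs of replicates, 0 were identical, and the smallest chi-square per degree of freedom between replicates was 66.9, so no replicate was a copy or resampling of another.

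Genes were tested with edgeR 4.0.16 in R 4.3.3 by robust quasi-likelihood fits with TMM scaling, after filterByExpr by group. The 3 genotypes of a stage were fitted together without a block, the control stages apart, and differences of a genotype effect between stages in a joint fit of all 28 libraries. Benjamini-Hochberg adjusted p-values were taken over all genes of a comparison, with a threshold of 0.05, and tests were two-sided. Genes tested numbered 16470 in ESCs, 16783 in NPCs, 17931 in neurons, 18365 in the control stages and 19996 in the joint fit. Log2 fold changes are given with SE, and mean CPM with SD over libraries. Log2 CPM used a prior count of 2. Where a group held 0 counts, a floor of 3 counts over the group gives a lowest fold; where it held 1 to 3 counts, a ratio is given with its exact 95% binomial interval. Intervals and floors cover counting error only.

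Before the data were examined, the comparisons, the tests, 44 gene lists and the rule for named genes were fixed. The lists cover the 7qF3 interval and its flanks, the protocadherins, cell identities, signalling and stress responses, imprinted genes and housekeeping groups. Of these, 43 had at least 3 members tested; the mitochondrially encoded list had 1. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison; fry of limma tested whether members changed in either direction. Camera compares a list with the other genes; an adjusted p printed for a list is camera's, with the preset correlation unless stated otherwise. The lists hold 785 genes, 31 of them in more than 1 list. For clustered protocadherins, the series title names the gene family, so these lists may have been chosen on these samples and are not independent evidence.

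Genes were named by rule: Aldoa, Mapk3, Kctd13, Taok2, Maz and Ppp4c of the interval; the 8 largest changes in each direction (5 between mutants and between control stages) among genes past the threshold with mean CPM of at least 5 and no overlap between the libraries; and members of each clustered protocadherin list and each called list, up to 4 past the threshold with the smallest p, or 2 with the smallest p where none passed. Interaction contrasts named up to 5 genes in each direction.

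Whether same-numbered libraries belong together was checked from the correlation of their deviations from group means. In ESCs all 9 pairs had correlations between 0.224 and 0.692, so the ESC numbers pair the samples, from the data and not from a label; blocked values stand beside ESC results where they change a call. In NPCs and neurons some pairs had correlations below 0.1, so the numbers were not taken as pairs.

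Scripts that test genes and lists were tested on simulated data with 200 genes changed. At 4-fold, edgeR recovered 47% of them in the ESC deletion design, 61% in that of NPCs and 25% in that of neurons; at 2-fold it recovered 4%, 8% and 1%. A count of 0 called genes in these designs is therefore weak evidence against changes of 2-fold.

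Results were recomputed with the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR and no filter on low counts. Genes alone had limma-voom, only the groups compared and a minimum absolute log2 fold change of 1. Interactions skipped these, a replicate block and all 28 libraries in 1 fit. Only tests by chromosome used mean CPM of at least 5. Each library was left out in turn. In mutant neurons this leaves an arm of 1 library, and the spread comes from the other groups alone. After the data were seen, a batch term for depth or mitochondrial share, a fit without shallow libraries and summed synonymous entries were added. A planned test on TPM per library was not run.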

Results

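Total RNA was sequenced from mouse cells with altered copy number of 7qF3, the part of chromosome 7 that corresponds to human 16p11.2, a region whose loss or gain is associated with autism. Deletion cells carried 1 copy of the region. Duplication-deletion cells carried a duplicated and a deleted chromosome, which gives 2 copies in all, as in control cells, but on a single chromosome. Libraries came from ESCs (3 control, 3 deletion, 3 duplication-deletion), from NPCs at day 5 (5, 3 and 3) and from immature dopaminergic-lineage neurons at day 16 (4, 2 and 2). The values were deposited expected counts per gene. Total counts per library ran from 35672610 to 69523477 in ESC replicates 1 and 2, and were 20814862, 5578151 and 22935331 in replicate 3 of control, deletion and duplication-deletion. In NPCs they ran from 48630461 to 78814037, except in replicate 5, with 23561794, 24053970 and 19311982 for the same genotypes; these replicates are called the shallow libraries. Neuron libraries had 41892753 to 56031950 counts. The labels do not say whether replicates were separate cultures or lines, so p-values measure only the spread between these libraries.

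Control cells passed from the pluripotent state to a midbrain-like neural progenitor between ESC and NPC. Genes of the naive pluripotent state fell, among them Esrrb, a nuclear receptor of the pluripotency network, and Fgf4, a growth factor that ESCs secrete. Genes of dividing neural progenitors rose, such as Vim, an intermediate filament, Sox9, a transcription factor of neural stem cells, and Neurog2, a proneural factor. Midbrain floor plate genes were higher as well, including Shh, the ventralising signal, and Lmx1a, which specifies dopaminergic progenitors. Protocadherin genes, whose products give neurons distinct surface identities, were higher in all 3 clusters. The midbrain and cluster calls were lost with an estimated correlation (adjusted p from 0.199 to 0.369).

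The question of the control comparisons is which changes belong to differentiation itself. Control NPCs (n = 5) against control ESCs (n = 3) had 7630 genes past the edgeR threshold, 3857 higher and 3773 lower. All 22 naive pluripotency genes were lower, with a median log2 fold change of -11.29, or -10.69 with genes at 0 counts set at their bound (adjusted p = 1.99e-31, adjusted p = 5.27e-05 with an estimated correlation). Esrrb had 2.31 ± 1.07 CPM in NPCs against 272 ± 51.8 in ESCs (log2 fold change -6.86 ± 0.447). Fgf4 had -12.76. All 10 genes of the 2-cell-like state, a rare totipotent-like condition of ESCs, were lower (median -11.79, at bound -9.71, adjusted p = 1.01e-19, adjusted p = 0.0111 with an estimated correlation), and Zscan4f was at least 29900-fold lower. Of 15 neural progenitor genes 13 were higher (median 4.03, adjusted p = 4.02e-11, adjusted p = 0.00666 with an estimated correlation). Vim had 1240 ± 259 CPM against 123 ± 14.4 (3.33), Sox9 rose by 6.80 and Neurog2 was at least 1030-fold higher. Ventral midbrain progenitor genes had a median of 5.31, with 15 of 17 higher (adjusted p = 1.31e-07, adjusted p = 0.199 with an estimated correlation). Shh had 97 ± 77.2 CPM in NPCs (9.23) and Lmx1a 68.7 (5.80). Pcdha (median 5.66, at bound 3.07, 8 of 14 higher, adjusted p = 0.0248) and Pcdhg (13 of 22 higher and 2 lower, adjusted p = 0.000617) rose too, each with adjusted p = 0.369 with an estimated correlation. The Pcdhb cluster had a median of 6.14, at bound 4.86 (19 of 21 higher, adjusted p = 6.44e-10, adjusted p = 0.265 with an estimated correlation). Non-clustered protocadherins such as Pcdh7 and Pcdh10, adhesion molecules of developing brain, had a median of 5.63 (10 of 12 higher, adjusted p = 7.22e-09, adjusted p = 0.00666 with an estimated correlation). The 7qF3 interval itself changed with stage, with 11 of 31 genes lower and 1 higher (median -0.52, adjusted p = 0.0193, adjusted p = 0.455 with an estimated correlation), led by the glycolytic enzyme Aldoa (-2.69).

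From NPC to neuron, control cells left the cell cycle and acquired transmitter genes. Top2a and Mcm3, which act in DNA replication and chromosome segregation, fell, and so did Lin28a and Hmga2, regulators of early progenitors. Dopaminergic genes rose, including Ddc, which makes dopamine from its precursor, and Aldh1a1, a marker of midbrain dopaminergic neurons, though as a list they had adjusted p = 0.13 with an estimated correlation. Mapt, a microtubule protein of axons, and Gfap, a filament of astrocytes, rose too.

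Control neurons (n = 4) against control NPCs (n = 5) had 8023 genes past the threshold, 4258 higher and 3765 lower. All 20 proliferation genes were lower (median -4.13, adjusted p = 3.22e-50, adjusted p = 0.00185 with an estimated correlation); Top2a had 46.3 ± 7.06 CPM against 846 ± 64.2 (-4.19 ± 0.217). Of 15 dopaminergic genes 13 were higher (median 5.36, adjusted p = 6.45e-09, adjusted p = 0.13 with an estimated correlation). Ddc had 147 ± 23.8 CPM against 3.36 ± 1.51 (5.47 ± 0.332), Aldh1a1 had 176 ± 55.1 against 1.79 (6.62), and the acetylcholine receptor gene Chrnb3 was at least 2530-fold higher. Pan-neuronal genes had a median of 2.55 (17 of 19 higher, adjusted p = 3.76e-10, adjusted p = 0.181 with an estimated correlation), with Mapt at 472 ± 116 CPM against 11.6 (5.34). Astrocyte genes had a median of 2.33 (8 of 11 higher, adjusted p = 1.11e-05, adjusted p = 0.0163 with an estimated correlation), with Gfap at 76.7 ± 27.3 CPM (10.63). Lin28a had -7.68 and Hmga2 -6.99.

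In deletion ESCs the genes of the 7qF3 interval fell to near the level that 1 copy predicts. Among them were Taok2, a kinase that shapes dendrites, Maz, a zinc finger transcription factor, Kif22, a spindle motor, and Cd2bp2, a splicing factor. Genes of cytosolic ribosomal proteins, which build the translation machinery, were slightly lower with the preset correlation only (adjusted p = 0.851 with an estimated correlation).

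The comparison asks what loss of 1 copy changes in undifferentiated cells (n = 3 each). With edgeR 0 of 16470 genes passed the threshold and 207 had an unadjusted p below 0.05; DESeq2 called 6, limma-voom 0, and the authors' deposited table called 3, all lower. With the replicate block, chosen for ESCs from the data, 9 genes passed, all lower and all in the interval. They included Aldoa (357 ± 132 CPM against 927 ± 321; blocked log2 fold change -1.39, adjusted p = 0.000309), Taok2 (14.8 ± 3.79 against 35.2 ± 6.77; -1.27, adjusted p = 0.00441), Kif22 (23.3 ± 2.48 against 58.4 ± 4.56; -1.33, adjusted p = 0.00551), Cd2bp2 (23.2 ± 2.6 against 48.6 ± 1.58; -1.07, adjusted p = 0.00551) and Maz (17.3 ± 4.78 against 39.8 ± 3.44; -1.23, adjusted p = 0.00715). Of 29 interval genes 28 were negative, with a median of -1.22 (adjusted p = 5.06e-44, adjusted p = 0.0107 with an estimated correlation), and 15 were lower when adjusted over the list alone. Outside those calls, Ppp4c, a phosphatase subunit, had -1.22 ± 0.237 and Mapk3, the kinase ERK1, -0.98 ± 0.548, while Kctd13, an adaptor of a ubiquitin ligase, had -0.41 ± 0.467, within its error. The median interval gene stood at 45.5% ± 3.66 of the control mean (SD, n = 3), with libraries from 41.4% to 48.5%, against 97.7% ± 6.46 in control ESCs.

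**Figure D1:**
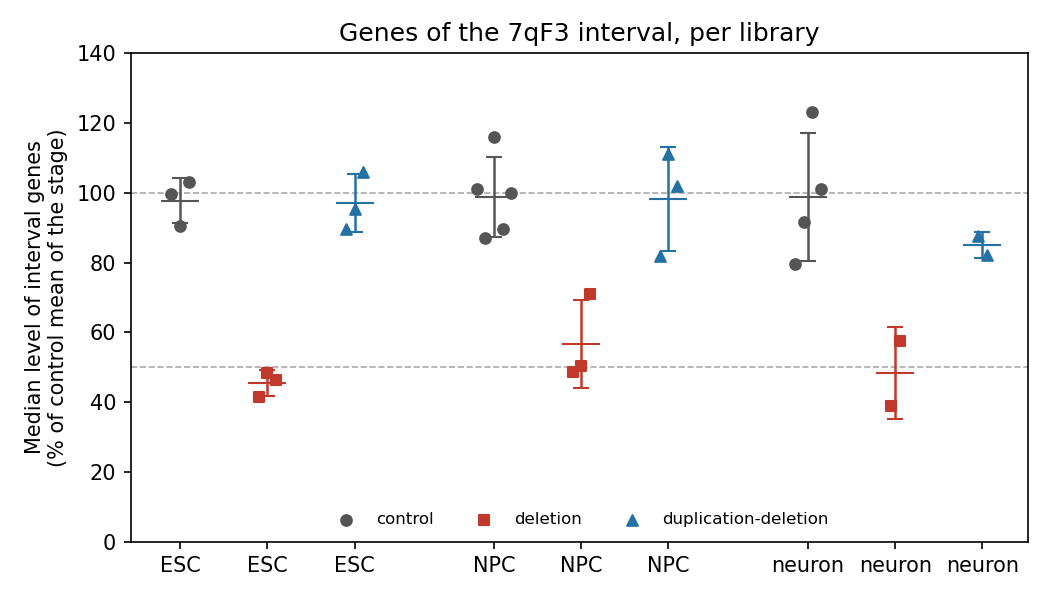
Median level of interval genes in each library as a percent of the control mean of the stage; symbols are libraries, horizontal bars with whiskers are mean ± SD of the group. Deletion libraries lie between 39% and 71.1%, and the groups with duplication and deletion have means of 97%, 98.3% and 84.9% in ESCs, NPCs and neurons.

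Ribosomal protein genes had a median of -0.33 in deletion ESCs, with 72 of 76 negative (adjusted p = 4.09e-11, adjusted p = 0.851 with an estimated correlation); Rpl36 had -0.78 and Rps26 -0.58. With the block, 29 of them were lower when adjusted over the list alone. A further 3 lists were called but depended on single libraries, each left out alone, and their adjusted p with an estimated correlation ran from 0.851 to 0.92. The 2-cell-like genes had a median of 0.40 (9 of 10 positive, adjusted p = 0.0233), a call lost without control replicate 2 (0.47), control replicate 3 (0.19), deletion replicate 1 (0.07) or deletion replicate 2 (0.38), and 0.66 and 0.61 without control replicate 1 and deletion replicate 3. Autism risk genes, among them the chromatin regulators Ash1l (0.47) and Adnp (0.40), had a median of 0.24 (27 of 36 positive, adjusted p = 0.00505), lost without control replicate 3 (0.09), deletion replicate 1 (0.08) or the shallow libraries (0.16), and 0.46 without control replicate 1. Histone genes had a median of -0.48 (40 of 42 negative, adjusted p = 5.6e-06), lost without control replicate 3 (-0.09) or deletion replicate 1 (-0.29), and -0.75 and -0.89 without control replicate 2 and deletion replicate 3. With the block, glycolysis genes (-0.13) and X and Y genes (0.21) were called in addition (adjusted p = 0.0492 each, adjusted p = 0.825 and 0.733 with an estimated correlation). The Pcdhg cluster had a median of 0.34, not past the threshold (adjusted p = 0.261).

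Duplication-deletion ESCs kept interval genes near the control level, and their 2-cell-like genes were higher with the preset correlation only (adjusted p = 0.197 with an estimated correlation). These include Zscan4f, a telomere regulator of the transient 2-cell-like state, and Gm8300. With the replicate block imprinted genes of distal chromosome 7 also changed: among them Kcnq1ot1, the silencing RNA of its cluster, rose, and Cdkn1c, a growth-restraining cell cycle inhibitor of that cluster, fell.

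This comparison holds copy number at 2 and asks what the rearranged chromosomes change (n = 3 each). With edgeR 0 genes passed and 51 had an unadjusted p below 0.05; DESeq2 called 3, limma-voom 0, and the authors' deposited table called 5, all lower. With the replicate block 7 genes passed: Kcnq1ot1 (1.17, adjusted p = 0.0102), Zscan4f (0.87, adjusted p = 0.0181) and Zscan4e (0.92, adjusted p = 0.0181) were higher. Cdkn1c (-1.29, adjusted p = 0.0102), Phlda2 (-1.38, adjusted p = 0.0132), D7Ertd715e (-2.23, adjusted p = 0.0132) and Snurf (-2.44, adjusted p = 0.0441) were lower; all but Zscan4f were chosen after their values were seen. D7Ertd715e and Snurf overlap the Snrpn transcript, so their counts may belong to it. All 10 of the 2-cell-like genes were positive (median 0.74, adjusted p = 6.84e-10, adjusted p = 0.197 with an estimated correlation, 0.0928 with the block), 5 of them higher with the block when adjusted over the list alone, and the median was 0.49 without duplication-deletion replicate 1. Zscan4f had 470 ± 195 CPM against 258 ± 99.4 and Gm8300 21.7 ± 1.85 against 13.1 ± 4.93 (0.73 ± 0.296). Across the interval the median was -0.04 (adjusted p = 0.812): Taok2 had -0.06, Aldoa -0.20, Mapk3 -0.22, Kctd13 -0.19, Maz 0.11 and Ppp4c -0.04, each within error. The Pcdhg cluster had a median of 0.27 (adjusted p = 0.138), which was called without control replicate 1 (0.33) or without duplication-deletion replicate 2 (0.39). With the block, imprinted genes had 3 higher and 6 lower when adjusted over the list alone, and glycolysis (adjusted p = 0.0261) and histone genes (-0.19, adjusted p = 0.00217) were called in addition (adjusted p = 0.895 each with an estimated correlation). Pcdha and Pcdhb were barely transcribed in ESCs, with sums of 0.243 to 1.04 CPM per group.

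Between the mutant ESCs, which differ in interval copy number, 0 genes passed with edgeR and 164 had an unadjusted p below 0.05 (DESeq2 15, limma-voom 0; 1 was called without duplication-deletion replicate 3). With the block 13 passed, 3 higher and 10 lower in deletion cells. Interval genes had a median of -1.16 with 28 of 29 negative (adjusted p = 3.39e-47, adjusted p = 0.00827 with an estimated correlation) and 15 lower when adjusted over the list alone; Kif22 had -1.22 with the block (adjusted p = 0.00812), and 2900092E17Rik -1.60 (adjusted p = 0.00375). Cdkn1c was higher in deletion cells, with 31.1 ± 8.83 CPM against 11 ± 3.74 (blocked log2 fold change 1.51, adjusted p = 0.0022). The other 6 called lists each lost the call without some library, and their adjusted p was 0.929 with an estimated correlation. They were ribosomal (-0.31, adjusted p = 1.84e-08), 2-cell-like (-0.39, adjusted p = 0.0479), dopaminergic (-0.91, adjusted p = 0.0438), autism risk (0.15, adjusted p = 0.0479), histone (-0.38, adjusted p = 0.0343) and imprinted genes. For imprinted genes the median was -0.02, the mean was 0.05 and the test pointed up (adjusted p = 0.0454). With the block the dopaminergic and imprinted lists were not called (adjusted p = 0.159 each).

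In deletion NPCs Pcdhgb2, an isoform of the Pcdhg cluster, fell. With the preset correlation, the Pcdha and Pcdhb clusters were higher, and so were forebrain transcription factors, among them Dlx1 and Dlx2, which specify inhibitory neurons of the ventral forebrain, and Eomes, a factor of intermediate progenitors. Genes of cholesterol synthesis were slightly higher and genes of neural crest and of the interferon response lower. With an estimated correlation none of these lists was called (adjusted p from 0.0562 to 0.381).

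The comparison asks what 1 copy of the interval changes in neural progenitors (n = 3 against n = 5). Pcdhgb2 (mm9 chromosome 18, 37849513 to 38001526) alone passed the edgeR threshold among 16783 genes, with 3.51 ± 0.697 CPM against 36.5 ± 14.5 (log2 fold change -3.37 ± 0.396, adjusted p = 0.0235), and 598 genes had an unadjusted p below 0.05. DESeq2 called 102, limma-voom 0, a term for batch 12, and the authors' deposited table called 122, with 31 higher and 91 lower. The Pcdhgb2 call was lost without control replicate 1 (-3.37, adjusted p = 0.0905), control replicate 3 (-3.42, adjusted p = 0.0793), deletion replicate 1 (-3.37, adjusted p = 0.175), deletion replicate 3 (-3.53, adjusted p = 0.101), deletion replicate 5 (-3.25, adjusted p = 0.085) or the shallow libraries (-3.32, adjusted p = 0.0737). Across the interval the median was -0.70, with 26 of 29 negative and 11 lower when adjusted over the list alone (adjusted p = 9.05e-15, adjusted p = 0.107 with an estimated correlation). Taok2 had 29.2 ± 7.94 CPM against 54.9 ± 4.81 (-0.91 ± 0.207), Ino80e 10.3 ± 0.609 against 21.2 ± 4.73 (-1.04 ± 0.26), Aldoa -0.94, Mapk3 -0.91, Ppp4c -0.90, Maz -0.70 and Kctd13 -0.51. The median interval gene stood at 56.7% ± 12.5 of the control mean (SD, n = 3), with libraries at 48.7%, 50.3% and 71.1%, against 98.7% ± 11.5 in control NPCs (n = 5).

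All 21 Pcdhb genes were positive in deletion NPCs (median 1.61, adjusted p = 2.26e-32, adjusted p = 0.107 with an estimated correlation), and 13 were higher when adjusted over the list alone, which is not independent evidence because the study may have chosen the family on these samples. Pcdhb19 had 25.5 ± 10.5 CPM against 8.26 ± 1.57 (1.63 ± 0.292) and Pcdhb17 24.8 ± 11 against 5.75 ± 2.53 (2.11 ± 0.396). Summed over the cluster, Pcdhb counts reached 329% ± 151 of the control mean (SD, n = 3), with libraries from 166% to 463% against 53.6% to 166% in controls. The Pcdha cluster had a median of 1.37 with 13 of 14 positive and 0 adjusted over the list alone (adjusted p = 5.33e-07, adjusted p = 0.107 with an estimated correlation), and its sum reached 184% ± 20.6. The Pcdhg cluster had a median of -0.67, with 15 of 22 negative and 5 lower and 1 higher when adjusted over the list alone (adjusted p = 7.82e-08, adjusted p = 0.381 with an estimated correlation); its median was -0.40 without deletion replicate 5 (adjusted p = 0.0585) and -0.40 without the shallow libraries (adjusted p = 0.105). Counts within a cluster come from shared exons or near-identical genes, so values of single isoforms are uncertain.

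**Figure D2:**
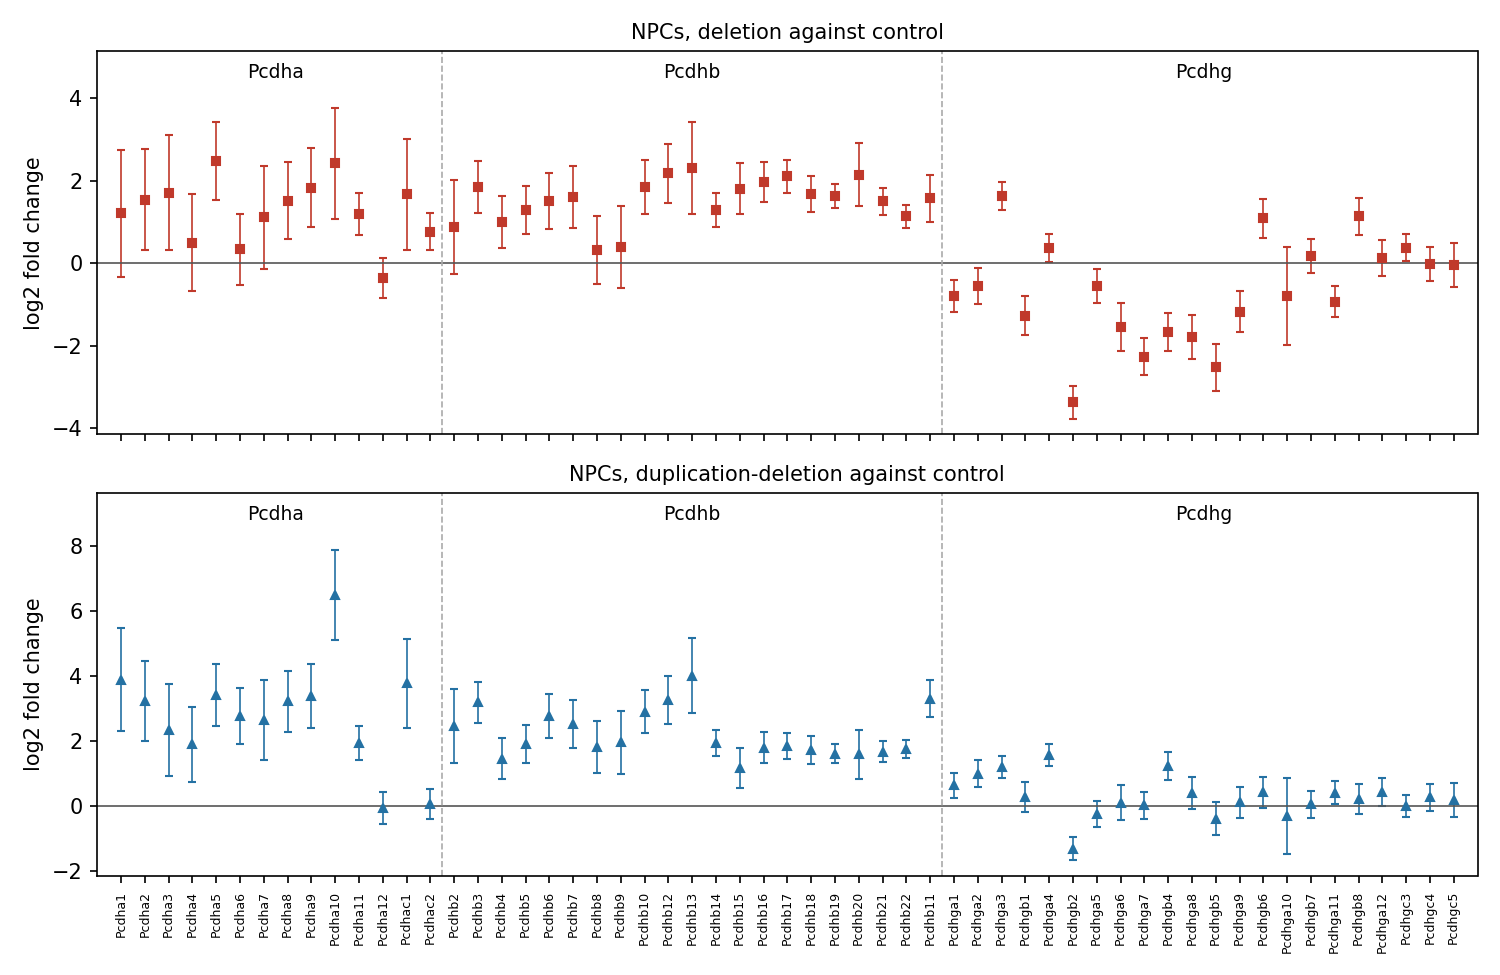
Log2 fold change against control of each clustered protocadherin gene in NPCs with deletion (squares, n = 3 against n = 5) and with duplication and deletion (triangles, n = 3 against n = 5), in order along chromosome 18 except Pcdhb11, placed last in its cluster; bars are ± SE. Pcdhb medians are 1.61 and 1.91, and Pcdhgb2 is lowest in each panel at -3.37 and -1.31.

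Forebrain genes had a median of 2.99 in deletion NPCs, with 12 of 13 positive and 7 higher when adjusted over the list alone (adjusted p = 4.86e-15, adjusted p = 0.0562 with an estimated correlation), and the median was 1.47 without deletion replicate 3. Dlx1 had 17.5 ± 15.5 CPM against 1.62 ± 1.08 (3.43 ± 0.739), Eomes 7.2 ± 3.81 against 0.911 ± 0.439 (2.99 ± 0.638) and Dlx2 3.67 ± 3.02 against 0.41 ± 0.252 (3.14 ± 0.772). GABAergic genes, which share the Dlx factors, had a median of 0.89 (9 of 12 positive, 3 higher when adjusted over the list alone, adjusted p = 1.22e-05, adjusted p = 0.227 with an estimated correlation), or 0.59 without deletion replicate 1. Cholesterol synthesis genes had a median of 0.28 with 18 of 18 positive (adjusted p = 9.55e-05, adjusted p = 0.381 with an estimated correlation), led by Hmgcs1, an early enzyme of the pathway, with 820 ± 212 CPM against 525 ± 127 (0.64 ± 0.244). Neural crest and mesenchyme genes fell (median -1.32; 11 of 13 negative, adjusted p = 2.36e-07, adjusted p = 0.107 with an estimated correlation); Snai2, a factor of migrating crest cells, had 0.558 ± 0.0502 CPM against 2.91 ± 2.15 (-2.37). Interferon response genes had a median of -0.92 with 12 of 16 negative (adjusted p = 0.000731, adjusted p = 0.221 with an estimated correlation), and for Ifit1, an antiviral protein, the control-to-deletion ratio was 20.8 (interval 6.97 to 102).

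**Figure D3:**
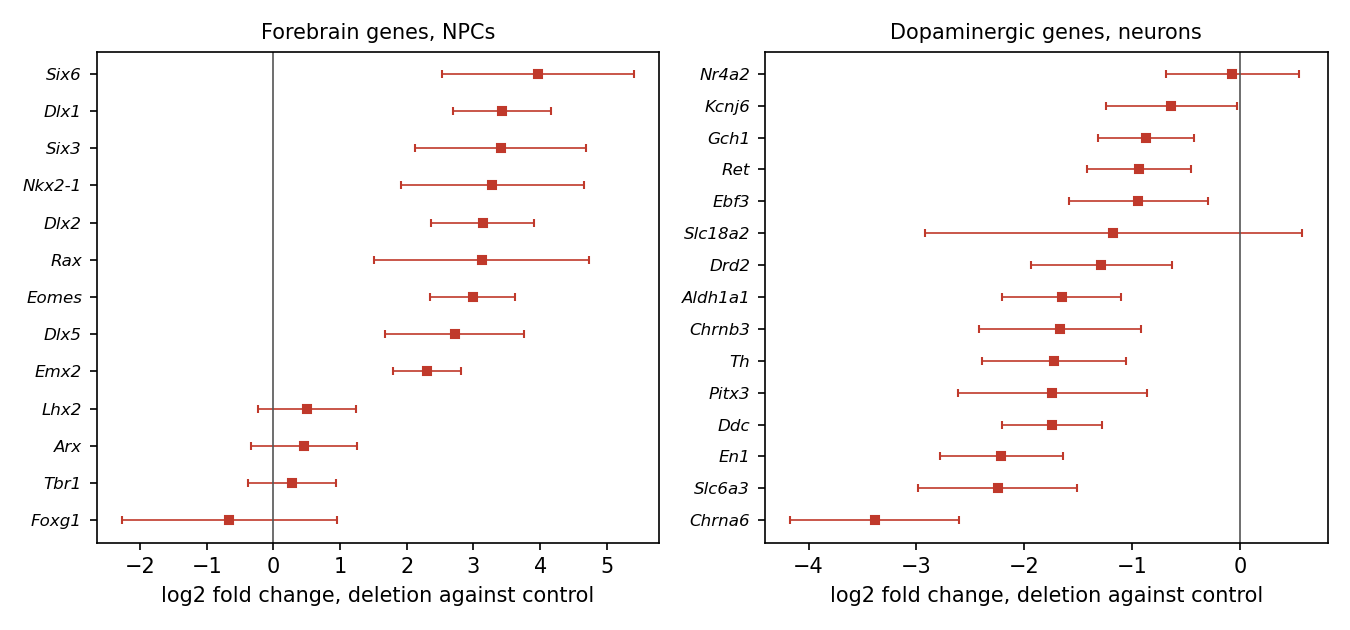
Log2 fold change of deletion against control for each forebrain gene in NPCs (left, n = 3 against n = 5) and each dopaminergic gene in neurons (right, n = 2 against n = 4), with bars of ± SE and without genes at 0 counts in a group. List medians are 2.99 and -1.66; Dlx1 lies at 3.43 and Chrna6 at -3.38.

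A further 8 lists were called in deletion NPCs but lost the call or changed direction without some library; with an estimated correlation their adjusted p ran from 0.124 to 0.758. Ventral midbrain genes had a median of -0.03 and a mean of -0.68 (adjusted p = 0.0207; 3 lower when adjusted over the list alone); En1 had 1.53 ± 1.02 CPM against 13.2 ± 10.3 (-3.13 ± 0.696). Their median ran from -0.17 to 0.11 over the libraries left out, reversed without control replicate 4, and the call was lost without deletion replicate 5 (-0.05) or the shallow libraries (-0.02). Neural progenitor genes had a median of 0.23 (12 of 15 positive, adjusted p = 0.0207), with Neurog2 at 1.27; the call was lost without control replicate 2 (0.18), control replicate 5 (0.19), deletion replicate 1 (0.16) or the shallow libraries (0.14), and the median was 0.53 without control replicate 1 and 0.14 without deletion replicate 5. Pan-neuronal genes had a median of 0.46 (17 of 19 positive, adjusted p = 0.00608), lost without control replicate 5 (0.37), reversed without deletion replicate 1 (-0.12) and 0.70 without deletion replicate 3. Autism risk genes had a median of 0.17 (30 of 37 positive, adjusted p = 0.0131), lost without control replicates 3 (0.18) and 5 (0.17) and deletion replicates 1 (0.14) and 3 (0.04); it was 0.29 without control replicate 4, 0.37 without deletion replicate 5 and 0.36 without the shallow libraries. Histone genes had a median of 0.58 (40 of 40 positive, adjusted p = 0.00859), lost without control replicate 4 (0.46) and reversed without deletion replicate 5 (-0.63, adjusted p = 1.73e-09) or the shallow libraries (-0.47). Glutamatergic, endoderm and fibroblast genes were called too and lost the call without several libraries in turn.

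In duplication-deletion NPCs, with 2 copies of the interval, the Pcdha and Pcdhb clusters rose as well. Imprinted genes changed in opposite directions: Zim1, a zinc finger gene of the Peg3 cluster that is normally read from the maternal chromosome, rose, while Airn, the paternal silencing RNA of the Igf2r cluster, fell. Plagl1, a growth regulator, and Ndn, a neuronal growth suppressor of the Snrpn region, fell. Pan-neuronal genes, such as Gap43 of growing axons, were higher as a list with the preset correlation only (adjusted p = 0.439 with an estimated correlation), and no member passed.

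The comparison asks what remains changed when copy number is 2 (n = 3 against n = 5). With edgeR 2 genes passed and 447 had an unadjusted p below 0.05; DESeq2 called 53, limma-voom 1, a term for batch 3, and the authors' deposited table called 54, with 29 higher and 25 lower. Zim1 (mm9 chromosome 7, 6628154 to 6649143) had 23.3 ± 5.48 CPM against 0.797 ± 0.486 (4.89 ± 0.457, adjusted p = 0.00186). Airn had 1 count over the group against 663, a ratio of 333 (interval 59.6 to 13200, adjusted p = 0.0482), and it overlaps Igf2r, so the strand of its counts is uncertain. The Airn call was lost, with adjusted p between 0.0634 and 0.398, without control replicates 1 (0.0682), 2 (0.0634), 4 (0.123) and 5 (0.0843), duplication-deletion replicates 2 (0.144), 4 (0.398) and 5 (0.0842), or the shallow libraries (0.138). The interval's median was 0.09, with 22 of 29 positive (adjusted p = 0.507), and stood at 98.3% ± 15 of the control mean (SD, n = 3). Aldoa had -0.32, Mapk3 0.17, Kctd13 0.22, Taok2 0.09, Maz -0.18 and Ppp4c 0.03, none past the threshold.

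All 21 Pcdhb genes were positive in duplication-deletion NPCs (median 1.91, adjusted p = 5.84e-66, adjusted p = 0.0184 with an estimated correlation), and 16 were higher when adjusted over the list alone, which is not independent evidence. Pcdhb11 had 36 ± 11.8 CPM against 3.64 ± 2.96 (3.30 ± 0.577) and Pcdhb22 16.6 ± 5.02 against 4.89 ± 0.716 (1.76 ± 0.276). The cluster sum reached 416% ± 163 of control (SD, n = 3), with libraries from 299% to 602%. The Pcdha cluster had 13 of 14 positive and 9 higher when adjusted over the list alone, again not independent evidence (median 2.99, adjusted p = 1.03e-22, adjusted p = 0.018 with an estimated correlation), and a median of 1.98 without the shallow libraries. Pcdha10 had 3.51 ± 3.4 CPM against 0.0398 ± 0.0562 (6.49 ± 1.39) and the cluster sum 387% ± 206, with libraries from 195% to 604%. The Pcdhg cluster had a median of 0.24 (18 of 22 positive; 2 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0188, adjusted p = 0.67 with an estimated correlation). Its call was lost without control replicates 1 (0.12) and 2 (0.12), its direction reversed without duplication-deletion replicate 4 (-0.07), and it was 0.44 and 0.50 without control replicate 4 and duplication-deletion replicate 2. Pcdhga4 had 20.1 ± 9.22 CPM against 6.81 ± 1.38 (1.56 ± 0.339) and Pcdhgb2 14.7 ± 5.81 against 36.5 ± 14.5 (-1.31 ± 0.353).

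Of the imprinted genes tested in duplication-deletion NPCs 18 of 29 were negative, with 2 higher and 8 lower when adjusted over the list alone (median -0.34, adjusted p = 9.19e-06, adjusted p = 0.302 with an estimated correlation); the test for change in either direction gave an adjusted p of 1.92e-07. The median was -0.19 without control replicate 5 and -0.19 without duplication-deletion replicate 4. Kcnq1ot1 had 1100 ± 164 CPM against 532 ± 195 (1.05) and Cdkn1c 46.8 ± 10.3 against 317 ± 173 (-2.76). Plagl1 had 11.2 ± 8.03 CPM against 125 ± 54.3 (-3.47), and Ndn 5.76 ± 5.13 against 29.8 ± 1.9 (-2.35). Kcnq1ot1 overlaps Kcnq1, so its counts may include that gene. Kcnq1ot1 and Ndn were chosen after their values were seen. Pan-neuronal genes had a median of 0.76 with 19 of 19 positive (adjusted p = 5.31e-10, adjusted p = 0.439 with an estimated correlation), or 0.38 without duplication-deletion replicate 4. Gap43 had 93 ± 17.5 CPM against 50.9 ± 9.06 (0.87 ± 0.346).

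**Figure D4:**
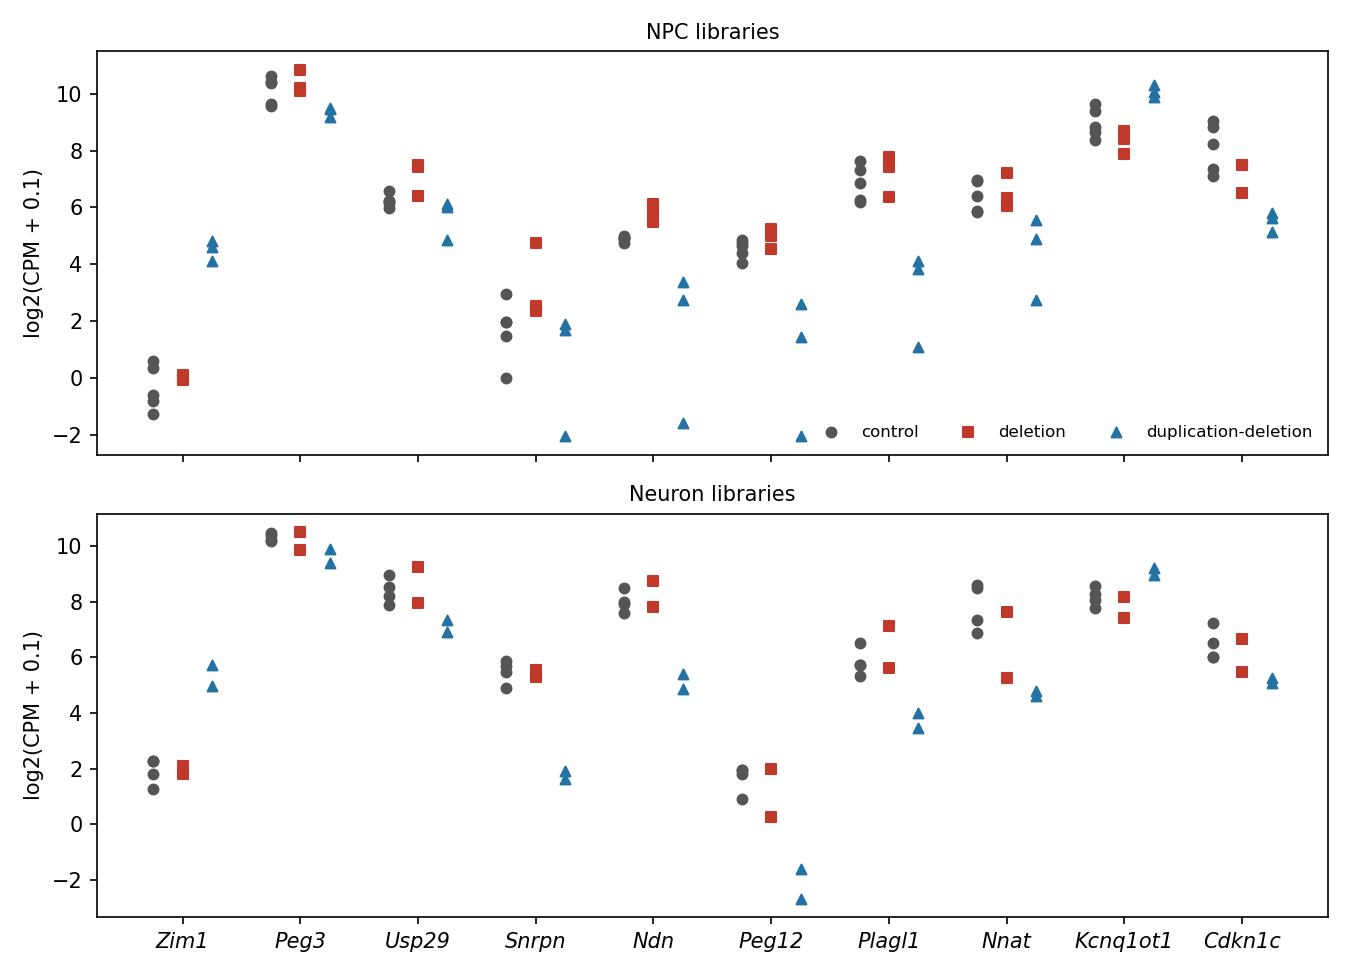
Log2(CPM + 0.1) of 10 imprinted genes in each NPC library (top) and each neuron library (bottom); circles are control, squares deletion and triangles duplication-deletion. Zim1 means in NPCs are 23.3 CPM in duplication-deletion against 0.797 in control, and in neurons 41.8 against 3.81.

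The other 10 called lists of duplication-deletion NPCs depended on single libraries, and with an estimated correlation their adjusted p ran from 0.302 to 0.738. Synaptic adhesion genes had a median of 0.34 (18 of 23 positive, adjusted p = 0.00591), lost without control replicate 5 (0.27) and duplication-deletion replicates 2 (0.48) and 4 (0.08), and 0.53 without duplication-deletion replicate 5. Ribosomal genes had a median of -0.18 (61 of 73 negative, adjusted p = 0.000921), lost without control replicate 3 (-0.08) and reversed without duplication-deletion replicate 4 (0.01); it was -0.28 and -0.08 without control replicates 4 and 5, -0.12 and -0.40 without duplication-deletion replicates 2 and 5, and -0.30 without the shallow libraries.

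Feedback targets of MAPK signalling in duplication-deletion NPCs, the pathway of the interval gene Mapk3, had a median of -0.11 (10 of 16 negative, adjusted p = 0.0224). That call was lost without control replicates 3 (-0.18) and 5 (-0.05) and duplication-deletion replicate 2 (-0.02), and the direction reversed without duplication-deletion replicate 4 (0.17). The median was -0.26, -0.02 and -0.19 without control replicates 1, 2 and 4, -0.74 without duplication-deletion replicate 5 and -0.64 without the shallow libraries. With an estimated correlation the adjusted p was 0.541. Wnt targets and genes of oligodendrocytes, blood, interferon response, glycolysis, cholesterol synthesis and proliferation were called as well and lost the call without several libraries in turn.

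Between the mutant NPCs, 4 genes passed with edgeR, 1 higher and 3 lower in deletion cells, and 673 had an unadjusted p below 0.05 (DESeq2 106, limma-voom 1, a term for batch 8). Zim1 had 0.902 ± 0.0664 CPM in deletion against 23.3 ± 5.48 (n = 3 each; -4.69, adjusted p = 0.0269). The uncharacterised genes 2210016F16Rik (-3.52, adjusted p = 0.0269) and 1700001L05Rik (-3.29, adjusted p = 0.0326) were lower too, and Airn was higher (534 counts against 1, ratio 558, interval 99.8 to 22100, adjusted p = 0.0269). Without deletion replicate 1, deletion replicate 3, duplication-deletion replicate 2, duplication-deletion replicate 4 or the shallow libraries the adjusted p was 0.121, 0.138, 0.096, 0.133 and 0.0557 for Zim1, 0.166, 0.22, 0.0533, 0.152 and 0.0659 for 2210016F16Rik, 0.166, 0.22, 0.184, 0.152 and 0.0849 for 1700001L05Rik, and 0.121, 0.0935, 0.184, 0.159 and 0.0849 for Airn. Without deletion replicate 5 it was 0.0566 for Zim1 and 0.118 for 1700001L05Rik.

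Interval genes had a median of -0.77 between the mutant NPCs (26 of 29 negative, 7 lower when adjusted over the list alone, adjusted p = 1.55e-13, adjusted p = 0.204 with an estimated correlation), with Cd2bp2 at -0.77. The Pcdhg cluster was lower in deletion cells (median -1.24; 17 of 22 negative and 11 lower when adjusted over the list alone, not independent evidence, adjusted p = 9.97e-13, adjusted p = 0.251 with an estimated correlation), or -0.73 without duplication-deletion replicate 4; Pcdhgb4 had 1.6 ± 0.719 CPM against 12.1 ± 4.66 (-2.91). Forebrain genes were higher (median 2.29; 12 of 13 positive, adjusted p = 5.23e-09, adjusted p = 0.152 with an estimated correlation), or 1.19 without deletion replicate 3, and neural crest genes were lower (-1.09; 12 of 13 negative, adjusted p = 5.23e-09, adjusted p = 0.152 with an estimated correlation), or -0.71 without the shallow libraries and -1.66 without duplication-deletion replicate 4. Cholesterol synthesis genes were higher (0.43; 18 of 18 positive, adjusted p = 2.4e-09, adjusted p = 0.213 with an estimated correlation), as were imprinted genes (0.74; 14 higher and 5 lower when adjusted over the list alone, adjusted p = 6.35e-07, adjusted p = 0.213 with an estimated correlation), or 0.43 without deletion replicate 3. Glycolysis genes, such as Pdk1 (1.15), had a median of 0.54 (15 of 17 positive, adjusted p = 6.9e-05, adjusted p = 0.344 with an estimated correlation), or 0.28 without deletion replicate 3. The other 12 called lists lost the call or changed direction without some library. Among these, Pcdha had -1.53 (adjusted p = 0.000233, adjusted p = 0.251 with an estimated correlation) and -1.23 without the shallow libraries (adjusted p = 0.11). Pcdhb had -0.65 (adjusted p = 0.000336, adjusted p = 0.532 with an estimated correlation) and lost the call without deletion replicate 5 (-0.45), duplication-deletion replicate 4 (-0.22) or the shallow libraries (-0.59); it was -0.99 and -0.98 without deletion replicates 1 and 3.

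In deletion neurons no gene passed with edgeR without a block. Genes of the dopaminergic identity were lower as a list with the preset correlation only (adjusted p = 0.297 with an estimated correlation). The list includes Chrna6, an acetylcholine receptor subunit of dopaminergic axons, and En1, a homeobox factor that keeps these neurons alive. Genes of the unfolded protein response, such as Ddit3 and Atf3 of stressed cells, and the Pcdhb cluster were higher as lists with the preset correlation only (adjusted p = 0.363 with an estimated correlation).

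The comparison asks what 1 copy of the interval changes in immature neurons (n = 2 against n = 4). With edgeR 0 of 17931 genes passed and 651 had an unadjusted p below 0.05; DESeq2 called 68, limma-voom 0, a term for batch 0, and the authors' deposited table called 44, with 10 higher and 34 lower. Interval genes had a median of -0.92, with 29 of 29 negative and 9 lower when adjusted over the list alone (adjusted p = 7.1e-14, adjusted p = 0.297 with an estimated correlation), or -1.50 without deletion replicate 3. Taok2 had 31.5 ± 13.9 CPM against 80.5 ± 19.2 (-1.35 ± 0.356), Mapk3 30.2 ± 0.515 against 51.4 ± 5.21 (-0.77 ± 0.243), Ppp4c -1.53, Maz -0.97 and Kctd13 -0.78. Aldoa, with 432 ± 161 CPM against 465 ± 166, had -0.11. The median interval gene stood at 39% and 57.6% of the control mean in the deletion libraries and at 98.8% ± 18.3 in controls (SD, n = 4).

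All 16 dopaminergic genes were negative in deletion neurons, with 5 lower when adjusted over the list alone (median -1.66, adjusted p = 9.98e-14, adjusted p = 0.297 with an estimated correlation). Chrna6 had 2.94 ± 1.45 CPM against 30.6 ± 14.4 (-3.38 ± 0.784) and En1 13.5 ± 0.792 against 62.6 ± 24.2 (-2.21 ± 0.569). Unfolded protein response genes had a median of 0.48 with 12 of 14 positive (adjusted p = 2.42e-05, adjusted p = 0.363 with an estimated correlation). Ddit3 had 23.2 ± 11.6 CPM against 7.73 ± 3.44 (1.58 ± 0.475) and Atf3 1.54. The Pcdhb cluster had a median of 0.43 with 20 of 21 positive (adjusted p = 3.7e-08, adjusted p = 0.363 with an estimated correlation), or 0.29 without control replicate 4. Pcdhb17 had 48.2 ± 2.69 CPM against 25.5 ± 8.54 (0.92). The Pcdhg cluster had a median of -0.38 with 15 of 22 negative, and 3 higher and 5 lower when adjusted over the list alone, not independent evidence (adjusted p = 0.000772, adjusted p = 0.363 with an estimated correlation), lost without deletion replicate 3 (-0.55, adjusted p = 0.42). Pcdhgb2 had 6.36 ± 0.0386 CPM against 72.9 ± 30.2 (-3.52 ± 0.461, adjusted p = 0.165) and Pcdhgb1 3.75 ± 0.484 against 22.5 ± 5.43 (-2.58 ± 0.353). The Pcdha cluster had a median of 0.46, not past the threshold (adjusted p = 0.0744), and 0.67 without control replicate 1 (adjusted p = 0.00152).

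The other 8 called lists of deletion neurons depended on single libraries, and with an estimated correlation their adjusted p ran from 0.267 to 0.69. Serotonergic genes such as Fev (-2.74) and Gata2 (-2.70) had a median of -1.94 (8 of 8 negative, 4 lower when adjusted over the list alone, adjusted p = 3.36e-10), -3.46 without deletion replicate 1 and lost without deletion replicate 3 (-1.67, adjusted p = 0.0628). Glycolysis genes such as Slc2a1 (1.41), had a median of 0.64 (16 of 16 positive, adjusted p = 3.7e-08), lost without deletion replicate 1 (0.21) and 0.42 without control replicate 2. Targets of p53 such as Eda2r (1.25), had a median of 0.59 (13 of 14 positive, adjusted p = 4.47e-05), lost without deletion replicate 1 (0.29). Ribosomal genes had a median of 0.29 (69 of 73 positive, adjusted p = 5.56e-06), 0.19 without control replicate 2, 0.56 without deletion replicate 1 and reversed without deletion replicate 3 (-0.12). Neural crest genes such as Ngfr (-2.06) had a median of -0.87 (8 of 12 negative, adjusted p = 0.00798), -0.55 without control replicate 4 and lost without deletion replicate 3 (-1.62). Cholesterol synthesis, trophectoderm and astrocyte genes were called too and lost the call without several libraries in turn.

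In duplication-deletion neurons several genes of imprinted regions changed. Zim1 rose, and transcripts of the Snrpn region, read from the paternal chromosome, fell: Snrpn, which encodes a splicing protein, and the overlapping RNAs D7Ertd715e, A330076H08Rik and A230057D06Rik, which may be parts of 1 long transcript. Cholesterol synthesis genes, such as the enzymes Dhcr7 and Mvd, were lower as a list, with no member past the threshold, and the Pcdhb cluster was higher. Neither held with an estimated correlation (adjusted p = 0.421 each).

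The comparison asks what changes in neurons when copy number is 2 (n = 2 against n = 4). With edgeR 7 genes passed, 2 higher and 5 lower, and 1295 had an unadjusted p below 0.05; DESeq2 called 163, limma-voom 6, a term for batch 21, and the authors' deposited table called 183, with 83 higher and 100 lower. Higher were Zim1 (41.8 ± 15.1 CPM against 3.81 ± 1.18; 3.46 ± 0.374, adjusted p = 0.0155) and AK017779, an entry that overlaps Marcks (134 ± 53 against 7.75 ± 2.97; 4.12 ± 0.372, adjusted p = 0.00742). Lower were D7Ertd715e (7.61 ± 0.258 against 113 ± 25.6; -3.89 ± 0.359, adjusted p = 0.00742), A330076H08Rik (1.6 ± 0.222 against 22.7 ± 5.25; -3.83 ± 0.363, adjusted p = 0.00742), Snrpn (3.32 ± 0.44 against 45.8 ± 12.2; -3.78 ± 0.381, adjusted p = 0.0101) and A230057D06Rik (-2.93 ± 0.369, adjusted p = 0.0476). Gcfc1 had 0 counts against 4183, at least 706-fold lower (adjusted p = 0.00742), but it is a second name of another entry, and summed with it the change was 0.06. The interval's median was -0.13 (adjusted p = 0.757): Aldoa had -0.51, Mapk3 -0.13, Kctd13 0.19, Taok2 -0.20, Maz -0.31 and Ppp4c -0.31.

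Each of the 7 calls in duplication-deletion neurons was lost without some library, though leaving out a duplication-deletion library leaves an arm of 1. Without duplication-deletion replicate 2 the adjusted p was 0.0932 for AK017779, Zim1 and Gcfc1, 0.173 for D7Ertd715e, 0.203 for A330076H08Rik, 0.274 for Snrpn and 0.537 for A230057D06Rik. Without duplication-deletion replicate 4 it was 0.34 for Zim1, 0.136 for Gcfc1, 0.26 for D7Ertd715e, A330076H08Rik and Snrpn, and 1 for A230057D06Rik. Without control replicate 2 it was 0.0929 for Zim1, 0.0535 for Gcfc1 and Snrpn, 0.0521 for D7Ertd715e and A330076H08Rik, and 0.188 for A230057D06Rik. Zim1 had 0.059 and 0.0698 without control replicates 1 and 3, and A230057D06Rik 0.0984, 0.082 and 0.131 without control replicates 1, 3 and 4.

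Of 28 imprinted genes tested in duplication-deletion neurons 16 were negative, with 2 higher and 10 lower when adjusted over the list alone (median -0.38, adjusted p = 0.000684, adjusted p = 0.421 with an estimated correlation); the test for change in either direction gave an adjusted p of 3.22e-06. Ndn had 35.9 ± 9.6 CPM against 264 ± 71.6 (-2.88), Nnat 25.9 against 259 (-3.32), and Kcnq1ot1 550 ± 65.4 against 295 ± 68.3 (0.90), all chosen after their values were seen. The Pcdhb cluster had a median of 0.72, with 19 of 21 positive and 4 higher when adjusted over the list alone, not independent evidence (adjusted p = 8.48e-10, adjusted p = 0.421 with an estimated correlation). Pcdhb11 had 62.2 ± 1.13 CPM against 18 ± 6.39 (1.79 ± 0.316) and Pcdhb2 16 ± 4.37 against 2.66 ± 1.42 (2.58 ± 0.48). Pcdha had a median of 0.13 (adjusted p = 0.968), and Pcdhg a median of 0.09 and a mean of -0.02 (adjusted p = 0.655), though Pcdhgb2 had 12.8 ± 0.787 CPM against 72.9 ± 30.2. Cholesterol synthesis genes had a median of -0.82 with 18 of 18 negative (adjusted p = 8.37e-09, adjusted p = 0.421 with an estimated correlation). Dhcr7 had 13.6 CPM against 31.1 (-1.19) and Mvd 17.9 against 44.4.

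The remaining 15 called lists depended on single libraries, and with an estimated correlation their adjusted p ran from 0.421 to 0.799. Dopaminergic genes had a median of 0.64 (12 of 16 positive, adjusted p = 0.0488), lost without control replicates 1 (0.50) and 4 (0.59), reversed without duplication-deletion replicate 2 (-0.78) and 1.40 without duplication-deletion replicate 4. Ventral midbrain genes had a median of 0.75 (11 of 16 positive, adjusted p = 0.0132), lost without duplication-deletion replicate 2 (0.63). Synaptic adhesion genes such as Cntn4 (-1.93) had a median of -0.71 (22 of 23 negative, adjusted p = 0.000647), lost without duplication-deletion replicate 4 (-0.58). Glycolysis genes such as Pgk1 (-1.21) had a median of -0.71 (14 of 16 negative, adjusted p = 0.000731), lost without duplication-deletion replicate 2 (-0.42). Cilia genes such as Rsph1 (1.97) had 9 of 10 positive and 2 higher when adjusted over the list alone (adjusted p = 0.000342), lost without duplication-deletion replicate 4 (0.34).

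Lists of non-clustered protocadherins, GABAergic and serotonergic genes, Wnt targets, mesoderm, endoderm, fibroblast, endothelial and blood genes were called in duplication-deletion neurons too, and each lost the call without several libraries in turn. X and Y genes had a median of -0.84, a mean of 0.48 and a test that pointed down (adjusted p = 0.0467; 1 higher and 3 lower when adjusted over the list alone), with Ddx3y at 13.1 ± 4.57 CPM against 70.3 ± 14.5; the call was lost without control replicates 1 (-0.74), 2 (-0.76) and 4 (-0.88) and duplication-deletion replicates 2 (-0.90) and 4 (-0.78).

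Between the mutant neurons (n = 2 each), 6 genes passed with edgeR, 5 higher and 1 lower in deletion cells, and 1586 had an unadjusted p below 0.05 (DESeq2 266, limma-voom 2, a term for batch 29). Higher were A330076H08Rik (4.17, adjusted p = 0.0137), D7Ertd715e (3.94, adjusted p = 0.0137), Snrpn (42.6 ± 5.53 CPM against 3.32; 3.68, adjusted p = 0.0232), A230057D06Rik (3.48, adjusted p = 0.0264) and Gcfc1 (at least 492-fold, adjusted p = 0.0137, with the same doubt about its name); AK017779 was lower (-4.45, adjusted p = 0.0246). All were lost without duplication-deletion replicate 2 (adjusted p 0.165 for Gcfc1, A330076H08Rik, D7Ertd715e and AK017779, 0.202 for Snrpn and 0.207 for A230057D06Rik) and without duplication-deletion replicate 4 (0.147 for Gcfc1 and AK017779, 0.158 for A330076H08Rik and D7Ertd715e, 0.163 for Snrpn and 0.251 for A230057D06Rik). Without deletion replicate 1 the adjusted p was 0.0551 for Snrpn, 0.105 for A230057D06Rik and 0.224 for AK017779, and without deletion replicate 3 it was 0.0838 for AK017779.

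Dopaminergic genes were lower in deletion than in duplication-deletion neurons (median -2.05; 15 of 16 negative and 9 lower when adjusted over the list alone, adjusted p = 2.87e-11, adjusted p = 0.327 with an estimated correlation), or -0.92 without duplication-deletion replicate 2. Chrna6 had 2.94 ± 1.45 CPM against 62.3 ± 62.7 (-4.41). Cholesterol synthesis genes were higher (1.18; 17 of 18 positive, 11 when adjusted over the list alone, adjusted p = 2.87e-11, adjusted p = 0.327 with an estimated correlation), led by Insig1 (1.67). Glycolysis genes were higher (1.37; 16 of 16 positive, 10 when adjusted over the list alone, adjusted p = 4.38e-11, adjusted p = 0.33 with an estimated correlation), or 0.83 without deletion replicate 1, with Vegfa at 2.08. Across the interval the median was -0.97 with 24 of 29 negative (adjusted p = 2.14e-06, adjusted p = 0.327 with an estimated correlation), -0.60 without deletion replicate 1 and -0.63 without duplication-deletion replicate 2. Neural crest genes such as Ngfr (-2.82) had a median of -1.55 with 11 of 12 negative (adjusted p = 0.000938, adjusted p = 0.327 with an estimated correlation), or -0.58 without duplication-deletion replicate 4. A further 12 lists were called and lost the call without some library. Among these, Pcdhg had -0.50 (adjusted p = 0.00331, adjusted p = 0.379 with an estimated correlation), lost without deletion replicate 3 (-0.79) and duplication-deletion replicate 4 (-0.28), and -0.80 without duplication-deletion replicate 2, and X and Y genes had a median of 0.85, a mean of -0.99 and a test that pointed up. Pcdha (0.27, adjusted p = 0.231) and Pcdhb (-0.06, adjusted p = 0.231) were not called.

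Whether a genotype effect differs between stages was tested directly with edgeR over 19996 genes. For the deletion, NPC minus ESC, 1 gene passed and 643 had an unadjusted p below 0.05: Rnf17 (-5.77, adjusted p = 0.0043), lost without NPC deletion replicate 1 (-5.29, adjusted p = 0.0691). For the deletion, neuron minus NPC, Col5a2 passed (6.29, adjusted p = 0.0181; 619 genes unadjusted). It was lost without NPC deletion replicate 3 (5.97, adjusted p = 0.227), NPC deletion replicate 5 (5.93, adjusted p = 0.181), neuron deletion replicate 1 (5.90, adjusted p = 0.151) and neuron control replicates 1 (0.0523), 2 (0.0731) and 3 (0.0667). The duplication-deletion effect of Zim1 was larger in NPCs than in ESCs (4.49, adjusted p = 0.00306; 534 genes unadjusted). For duplication-deletion, neuron minus NPC, 0 genes passed and 1004 had an unadjusted p below 0.05, while DESeq2 called 33.

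No list for an interval flank, naive or primed pluripotency, or Hox genes passed in any of the 6 comparisons of a mutant with control. By chromosome, 5 comparisons had calls, all lost with an estimated correlation. Chromosome 11 genes were lower in duplication-deletion ESCs than elsewhere (median difference -0.19 over 1267 genes, adjusted p = 1.99e-08, 0.789 with an estimated correlation). With the replicate block this held with an estimated correlation (adjusted p = 0.00413). The authors' deposited table placed several of the same genes at its smallest p-values: Kif22 (-1.32) in deletion ESCs, Pcdhgb2 (-3.38) and Dlx1 (3.43) in deletion NPCs, and Chrna6 (-3.36) in deletion neurons. The same libraries give no further evidence.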

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

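Tests of explanations and regroupings below were chosen after the results were seen.

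Imprinted genes changed in cells with duplication and deletion, 10 in NPCs and 12 in neurons over the list alone, with Zim1 higher and Snrpn-region and Plagl1 transcripts lower; NPC duplication-deletion replicate 5 was far the lowest at some of them (Ndn 0.238 and Peg12 0.143 CPM). Batch predicts lost calls with a batch term, but 10 in NPCs passed with the same sign. In neurons 12 did, but batches in or near balance over genotype cannot tell. Reads shared with an overlapping gene are an unlikely cause at most of the 8 of 14 distinct genes clear of other entries' deposited coordinates. Kcnq1ot1, among them, lies within Kcnq1. For the 6 that overlap, the test cannot tell. A switch of every locus towards the maternal pattern may explain part, but a chromosome 7 locus (Kcnq1ot1, Cdkn1c, Phlda2) went against it. An imprinting difference between cell lines, from genotype or culture, might remain and was not tested. Bisulfite sequencing of imprinting control regions in each line would settle it.

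Pcdhb genes were higher in NPCs of both mutants (medians 1.61 and 1.91, adjusted p = 0.107 and 0.0184 with an estimated correlation), with 1 and with 2 copies of the interval. With a batch term the medians were 1.78 and 2.05, but batches were near balance. Reads moved between near-identical copies would leave the summed counts unchanged, but the sums were higher by 1.72 ± 0.394 and 2.06 ± 0.395 (SE). A larger share of neuron-like cells would predict pan-neuronal medians of 2.00 and 2.35, above the observed 0.46 and 0.76, so such a share is unlikely as the sole cause. Differences between clones, or an effect of the rearranged chromosome that does not depend on copy number, could remain and were not tested.

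In deletion cells forebrain genes were higher in NPCs (2.99) and dopaminergic genes lower in neurons (-1.66), calls lost with an estimated correlation (adjusted p = 0.0562 and 0.297). With a batch term the medians were 2.91 and -1.73, and with 1 library left out those closest to 0 were 1.47 and -1.26. Batches in or near balance cannot tell. A single library is an unlikely sole cause in NPCs, but untestable in neurons with 1 deletion library left. A lower share of neurons would predict a pan-neuronal median of -1.28, but -0.27 was observed. Patterning that varied between differentiations, a clonal difference or younger cultures might remain and were not tested.

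Regrouping shows how often other groupings give as many calls. For NPC deletion 2 of 56 splits called as many genes as the real 1, and for NPC duplication-deletion 2 of 56 called as many as the real 2. Among the latter, the split of control replicates 2 and 5 with duplication-deletion replicate 5 called 364, which points to structure among these samples; with batch as a term the real grouping called 3. Control NPC against ESC (1 of 56 splits; next highest 3) and control neuron against NPC (1 of 100; next highest 4863) had the most calls of the splits drawn. In ESCs the real groupings called 0, which all 10 of 10 splits must match, so these counts, made without the replicate block, test nothing. Between mutant NPCs 1 of 10 called as many as the real 4 (next highest 0); 10 splits are too few for a share under 0.05.

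Single libraries stood far from the rest of their control group at 11 genes. Chance alone would mark about 1 in 20 genes tested in each group, so 6 of 86 and 5 of 87 genes lie near chance. In NPC controls (6 of 86 genes), replicate 4 had 63.9 CPM of Neurog2 and 1.23 of Cdh9, replicate 2 had 16.7 of Apob and 0.301 of Gata1, and replicate 3 had 20.9 of Etv4 and 2.25 of Notum. In neuron controls (5 of 87), replicate 1 had 11.5 CPM of Pcdha3 and 0 of Krt18, replicate 3 had 2.53 of Pcdhac1 and 32.9 of Col6a2, and replicate 4 had 0.439 of Kdm5d.

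Differences of effect between stages were marked for the genes Rnf17 (-5.78), Col5a2 (6.29) and Zim1 (4.49), and for 38 lists with the preset correlation; none held with an estimated correlation, where the smallest adjusted p values were 0.272, 0.385, 0.68 and 0.0541. Pcdha and Pcdhb were near 0 in ESCs, so their differences from ESCs say nothing about how ESCs respond. For the deletion, NPC minus ESC, the median difference over a list was 0.50 (interval), 0.29 (distal flank), 1.83 (Pcdhb), -0.72 (Pcdhg), 3.26 (forebrain), -1.24 (interferon), 0.41 (cholesterol), -1.45 (neural crest), 1.11 (histone) and 0.36 (ribosomal). For the deletion, neuron minus NPC, they were -0.72 (Pcdha), -1.02 (Pcdhb), -1.84 (forebrain), -2.02 (GABAergic), -1.85 (serotonergic), -0.71 (pan-neuronal), -0.41 (synaptic), 0.76 (p53), 0.33 (unfolded protein), 0.47 (glycolysis), 0.49 (fibroblast) and 0.30 (ribosomal). For duplication-deletion, NPC minus ESC, they were 3.29 (Pcdha), 1.91 (Pcdhb), 0.73 (pan-neuronal), -0.42 (MAPK) and -0.19 (imprinted). For duplication-deletion, neuron minus NPC, they were -2.91 (Pcdha), -1.41 (Pcdhb), -0.74 (other protocadherins), -1.94 (GABAergic), -1.02 (pan-neuronal), -1.24 (synaptic), 0.82 (Wnt), 0.60 (interferon), -0.75 (cholesterol), 0.42 (proliferation) and -3.90 (blood).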

How the results depend on the processing

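Merging entries, the batch term and leaving out shallow libraries were chosen after the data were seen. Other settings were planned.

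Across settings, 6979 named-gene values and 1912 list medians kept their side of the threshold. Of the rest, 110 and 4 became called, 138 and 475 lost the call, and 1 and 28 reversed. Counts of called genes were within 1.5 times the main count in 174 cases and moved in 85. In every setting run for lists the interval dropped in deletion cells and Pcdhb rose in NPCs of both mutants. Likewise forebrain genes rose in deletion NPCs and dopaminergic genes dropped in deletion neurons. Causes were untested unless given below.

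The number of genes called differed between tests. DESeq2 called 6, 3 and 15 genes in ESCs (deletion, duplication-deletion, and deletion against duplication-deletion), 102, 53 and 106 in NPCs, 68, 163 and 266 in neurons, and 37, 8, 31 and 33 for the interactions. Simulated data give part of the cause: with 4-fold changes in the neuron deletion design DESeq2 recovered 62% and edgeR 25%. DESeq2 called 49 unchanged genes in addition. limma-voom called 0 in all comparisons of a mutant with control except 1 in NPCs and 6 in neurons with duplication and deletion. One fit of all 28 libraries called 1, 0 and 1 in ESCs, 16, 15 and 25 in NPCs and 2, 1 and 6 in neurons; fits of only the groups compared called 0, 0, 0, 3, 1, 1, 0, 8 and 0 in the same order. No filter gave 14 and 26 for neuron duplication-deletion against control and deletion against duplication-deletion, and DESeq2 size factors gave 1 and 6 for duplication-deletion NPCs and neurons. Merging entries kept 4 of 7 calls in duplication-deletion neurons (not Gcfc1, D7Ertd715e and A230057D06Rik) and 4 of 6 between mutant neurons (not Gcfc1 and D7Ertd715e).

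A term for batch called 4, 2 and 6 genes in ESCs, 12, 3 and 8 in NPCs, and 0, 21 and 29 in neurons. Without the shallow libraries 2 genes were called in duplication-deletion ESCs and 3 between mutant ESCs; with fewer samples, Pcdhg in deletion NPCs had -0.40 (adjusted p = 0.105), and histone genes reversed in deletion NPCs (-0.47, adjusted p = 4.52e-08) and between mutant NPCs (-0.48, adjusted p = 7.43e-09), as did proliferation genes between mutant NPCs (-0.025). With batch as a term ventral midbrain genes reversed in deletion NPCs (0.023). Lists called were 3 without the shallow libraries in duplication-deletion ESCs and between mutant ESCs, and 2 in duplication-deletion ESCs with the batch term.

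The replicate block called 9, 7 and 13 genes in ESCs, 11, 2 and 2 in NPCs, and 13, 40 and 21 in neurons. In ESCs the paired numbers take up part of the spread. NPC and neuron numbers were not taken as pairs, as same-number correlations ran from -0.0307 to 0.481 and from 0.0819 to 0.495. The 2 calls between mutant NPCs included 0 of the main 4. The block reversed ventral midbrain genes in deletion NPCs (0.15), cholesterol genes in deletion neurons (-0.039) and endothelial genes between mutant neurons (0.32, adjusted p = 0.0321). It called 3 lists in duplication-deletion ESCs and 7 in duplication-deletion neurons, where 2 chromosomes were called.

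An estimated correlation lowered the number of lists called from 5 to 1 in deletion ESCs, 1 to 0 in duplication-deletion ESCs, 17 to 0 and 15 to 2 in NPCs, 13 to 0 and 18 to 0 in neurons, 7 to 1, 19 to 0 and 17 to 0 between mutants, 23 to 4 and 16 to 2 between control stages, and 10, 12, 5 and 11 to 0 in the interactions. Adjusted p became 0.107 for the interval, Pcdha and Pcdhb in deletion NPCs (-0.70, 1.37 and 1.61) and 0.381 for Pcdhg (-0.67), 0.67 for Pcdhg in duplication-deletion NPCs (0.24), 0.297 for the interval (-0.92) and 0.363 for Pcdhb (0.43) and Pcdhg (-0.38) in deletion neurons, and 0.421 for Pcdhb in duplication-deletion neurons (0.72). It called 0 chromosomes in each comparison. With genes of mean CPM of at least 5, 1 chromosome was called in deletion NPCs, 1 between mutant NPCs and 0 between mutant neurons.

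Other reversals were endoderm genes in duplication-deletion neurons with DESeq2 (-0.046) and with no filter (-0.067), imprinted genes between mutant ESCs with DESeq2 (0.020) and with no filter (0.0046), and Gcfc1 with synonymous entries merged (0.056), where its counts join another entry. DESeq2 called Pcdha in deletion neurons (0.47, adjusted p = 0.0378). One fit of all libraries called 7 lists in duplication-deletion neurons and 3 between mutant ESCs.

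Leaving out each library in turn gave 0 to 1 called genes in deletion NPCs, 1 to 3 in duplication-deletion NPCs, 0 to 8 between mutant NPCs, 0 to 1 in deletion neurons, 0 to 6 in duplication-deletion neurons, 0 to 17 between mutant neurons and 0 to 1 between mutant ESCs. Interactions had 0 to 2 (deletion, NPC minus ESC), 0 to 40 (deletion, neuron minus NPC) and 1 to 3 (duplication-deletion, NPC minus ESC). List counts ran from 2 to 6 and 2 to 11 in ESCs, 9 to 18 in duplication-deletion NPCs, 8 to 18 and 7 to 15 in neurons, 3 to 6 between mutant ESCs and 10 to 19 between mutant neurons. Medians in ESCs ran from 0.043 to 0.39 (Pcdhg, duplication-deletion; highest without duplication-deletion replicate 2, adjusted p = 5.72e-05), and between mutants from -0.11 to 0.14 (imprinted) and -0.71 to 0.17 (histone). In deletion NPCs they ran from -0.81 to -0.40 (Pcdhg), -0.17 to 0.11 (ventral midbrain), -0.12 to 0.70 (pan-neuronal) and -0.63 to 1.00 (histone). In duplication-deletion NPCs they ran from -0.071 to 0.50 (Pcdhg), -0.74 to 0.17 (MAPK) and -0.40 to 0.0076 (ribosomal). Between mutant NPCs they ran from -1.27 to 0.21 (dopaminergic), -0.87 to 0.11 (pan-neuronal), -0.18 to 1.16 (trophectoderm) and -0.79 to 1.00 (histone). In deletion neurons they ran from 0.22 to 0.67 (Pcdha), -0.55 to -0.30 (Pcdhg) and -0.12 to 0.56 (ribosomal), and in duplication-deletion neurons from -0.78 to 1.40 (dopaminergic) and -0.15 to 0.79 (fibroblast).

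Scaling by DESeq2 size factors shifted medians by at most 0.115.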

Other observations

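These values were chosen after being seen. Libraries of a stage fell into batches by depth or mitochondrial share. Mitochondrial counts were 39.7% to 48.8% in neuron replicates 1 and 2, and 24% to 30.4% in 3 and 4. NPC duplication-deletion replicate 5 was also far the lowest at Y-linked Uty (2.57 CPM), Eif2s3y (3.38) and Ddx3y (1.19). Yet Ddx3y was low in the whole group (16.6 and 8.72 in 2 and 4, DESeq2 -2.56 against control, adjusted p = 0.00111). The cause was not tested.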
